A study of Bifidobacterium pseudocatenulatum with 12 samples.

How the data were processed

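RNA was measured in 12 cultures of Bifidobacterium pseudocatenulatum MP80, 4 each on lactose, on 2'-fucosyllactose (2'-FL) and on lacto-N-fucopentaose I (LNFP-I), every sugar at 2% in basal MRS medium and every culture sampled at mid-log phase. Per the labels' protocols the cells were held in an RNA-stabilising reagent, lysed with lysozyme and mutanolysin, and their RNA was treated with DNase, depleted of ribosomal RNA and made into stranded libraries. The replicates were separate biological replicates, per the labels. The authors deposited a table per library with 1942 coding genes, identified by numeric feature IDs on contigs Ga0224696_11 (1912 genes) and Ga0224696_12 (30 genes). The aligner, its settings and whether counting used strand were not given in the sources used here. All 1942 gene lengths were multiples of 3, so lengths are coding lengths.

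The deposited counts were whole reads per gene, as total gene reads and unique gene reads, per the file headers. The deposited RPKM values were scaled by the authors to coding length and to a library total that back-calculated to 25.3 to 37.2 M mapped reads, of which 12.2% to 38.0% lay in the listed genes. The authors' files also held summary columns over the experiment, a range of the RPKM signal and a signed difference score with no fixed range, which were used only to see which libraries they span. With a tolerance of 1e-04, the range column in 11 of the 12 files equalled the range over the 11 libraries without 2'-FL A, and the file of 2'-FL A alone held the range over all 12. Here 2'-FL A was kept in every main test, since its label puts it in the 2'-FL group.

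Total gene reads were tested with edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) factors, edgeR's expression filter, which left 1902 genes, and a robust quasi-likelihood test on group means of all 12 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. The test, the samples, the covariates, the rule for named genes and most alternatives were fixed before the data were examined. On simulated counts with 200 of 1902 genes changed, the test recovered 77% of 2-fold and 93% of 4-fold changes for 2'-FL against lactose, with 0.585% of calls false. For LNFP-I against lactose it recovered 79% and 95%, with 4.92% of calls false, and for LNFP-I against 2'-FL 67% and 92%, with 3.05% of calls false. Each gene was simulated on its own, so these rates do not cover a library that departs across many genes.

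Gene lists for fucose, lactose and N-acetylhexosamine use, transport, stress, mobile elements and other functions had been fixed, but the files do not pair IDs with names, so no list was tested and no gene was given a function. At most 2 IDs that rose and 2 that fell are named per comparison: those with the largest fold changes past the threshold, with a mean of at least 10 CPM (reads scaled to library size) and no overlap between the 4 values of each group. Instead, genes were described by position. A region was a run of neighbouring genes on a contig called in the same direction with at least a 2-fold change, with single uncalled genes allowed between, and at least 4 called genes. This definition was chosen after the data were seen, and the regions were picked on these libraries for their calls. In the comparison that defined them, their size and their genes' calls and adjusted p are therefore not independent evidence. Strand was not in the files, so regions are not called operons. A region's level in a library was the mean log2 CPM (prior count 2) over its tested genes, printed as a geometric mean CPM. Its group difference is printed with the range of the 16 differences between single libraries, a 97.1% rank interval for 4 against 4. Positions are 1-based on the contigs of the deposited files.

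Replicates were compared before averaging by a chi-square of their counts. The smallest value per degree of freedom was 10.4, between 2'-FL C and 2'-FL D, so no pair differed by as little as sampling noise and all 12 libraries were counted. Alternatives were median-ratio, upper-quartile and no composition factors, other filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), only the groups compared, a replicate block, other thresholds, and each library left out. Unique reads, the longest region left out, and 2'-FL A and LNFP-I D left out together were added after the data were seen. So were the correlation and covariance of the responses without each library, the simulated and split controls without 2'-FL A, and letters A and B against C and D as a block or each alone. Of the tested genes, 77 had over 50% of their reads shared with other places and are uncertain.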

Results

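The transcriptome of Bifidobacterium pseudocatenulatum MP80, a gut bifidobacterium, was measured during growth on lactose, the control sugar, and on the human milk oligosaccharides 2'-FL and LNFP-I. 2'-FL is lactose with a fucose on its galactose, and LNFP-I is lacto-N-tetraose with a fucose on its terminal galactose. Each sugar was supplied at 2% to 4 cultures. The replicates carried the letters A to D, except for an LNFP-I replicate titled 1. Total gene reads ranged from 3.61 M in lactose B to 12.8 M in LNFP-I 1. They were 7.94, 9.94 and 5.82 M in lactose A, C and D, and 4.02, 9.26, 12.6 and 10.6 M in 2'-FL A to D. LNFP-I B, C and D had 8.18, 5.55 and 9.32 M. Between 97.5% and 99.3% of these reads were unique.

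The libraries separated mainly along a first principal component that held 81.6% of the variance of log2 CPM. On it the lactose libraries lay between -33.3 and -23.7 and the LNFP-I libraries between 21.1 and 53.5. 2'-FL B, C and D lay between -30.2 and -21.1, whereas 2'-FL A lay at 29.2. On the second component, with 6.13% of the variance, all 4 2'-FL libraries lay between 10.4 and 14.03 and the lactose libraries between -12.7 and -7.07. Across genes, the Spearman correlation of 2'-FL A was 0.847 to 0.869 with the other 2'-FL libraries and 0.952 to 0.959 with the LNFP-I libraries. Deviations of the libraries also mostly followed 2 sets of letters, chosen after the data were seen. With LNFP-I 1 counted with A and B, deviations from the group means correlated above 0 across genes in 20 of 24 pairs of libraries within A and B or within C and D, and in 2 of 24 pairs between these sets of letters. Deviations from a group mean sum to 0, so values above 0 within the sets force values below 0 between them on balance. The 2 counts are therefore not independent. By the replicate chi-square only the lactose libraries fell into these sets. The labels name no batch. Values within each set, with 2 libraries per sugar, are given with the leading regions and the counts.

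**Figure D1:**
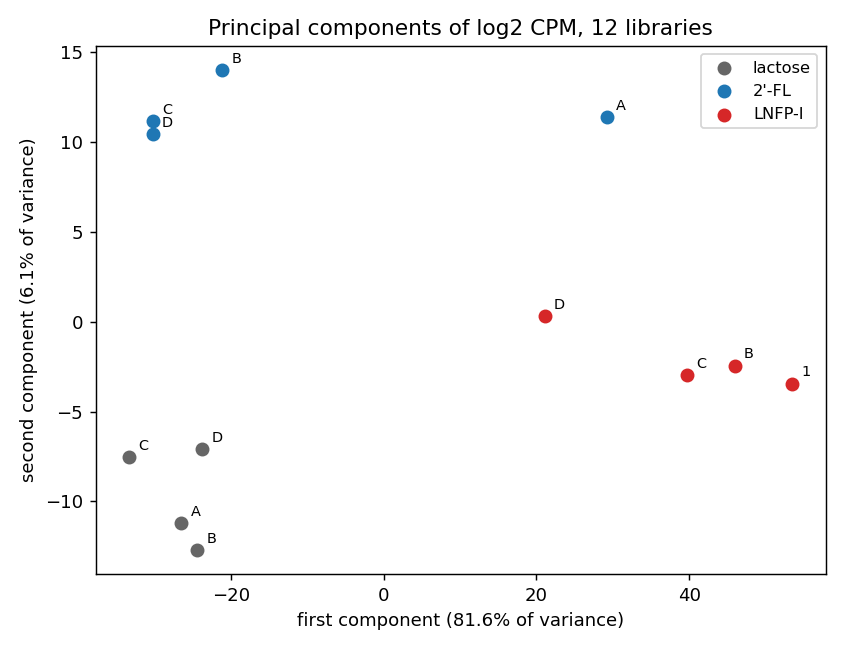
First against second principal component of log2 CPM for the 12 libraries, colored by sugar and marked with the replicate. 2'-FL A lies at 29.2 on the first component, with the LNFP-I libraries, and at 11.4 on the second, with the other 2'-FL libraries.

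The first comparison asked which genes change when 2'-FL replaces lactose. A 13.3-kb region of 12 genes on contig Ga0224696_11, from 2227375 to 2240645, rose 18.8-fold with 2'-FL (5.41 to 69.7 over single libraries, n = 4 per group). Its geometric mean level was 36 to 80 CPM in the lactose libraries and 2478, 1507, 492 and 435 CPM in 2'-FL A to D. All 12 genes passed the edgeR test, with adjusted p from 0.000982 to 0.0409. Of the genes past the threshold with a mean of at least 10 CPM and no overlap between the groups, those that rose most lay inside it. Gene 2765237619 (2233668 to 2234459) went from 56.4 ± 37.5 to 2662 ± 2310 CPM (SD, n = 4), a log2 fold change of 5.56 ± 0.73 (SE) with an edgeR adjusted p of 0.00118. Its neighbour 2765237620 (2234475 to 2235752) had a log2 fold change of 5.55 ± 0.71 and an edgeR adjusted p of 0.00111. Without 2'-FL A both log2 fold changes were 4.83. The region rose by 5.32 on the log2 scale within letters A and B and by 3.11 within C and D, where these genes had log2 fold changes of 3.82 and 3.87 (edgeR adjusted p = 0.0589 and 0.0527).

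Regions also fell with 2'-FL. In 7 neighbouring genes from 1069111 to 1075503 the level fell by 1.51 on the log2 scale (-2.09 to -1.03), from 589 to 864 CPM with lactose to 203 to 289 CPM with 2'-FL. They held the genes past the threshold with the largest decreases, 2765236614, with a log2 fold change of -1.78 ± 0.22 (SE, edgeR adjusted p = 0.00102), and 2765236613, with -1.64 ± 0.19 (edgeR adjusted p = 0.000982). In 4 genes from 2218042 to 2221961 the level fell by 1.07 on the log2 scale (-1.48 to -0.83), with adjusted p from 0.00177 to 0.00353. A group of 4 genes from 1889431 to 1894247 rose 2.57-fold (1.62 to 5.77), from 14.4 to 19.8 CPM to 32.01 to 83.1 CPM, with adjusted p from 0.0102 to 0.0490.

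Over all genes tested, 105 were higher and 122 lower with 2'-FL than with lactose (edgeR, 1902 genes), of which 31 and 19 changed at least 2-fold. In 386 genes, 20.3%, the 4 values of each group did not overlap, against 2.86% on average over all splits of the 8 libraries. Genes vary together, so a single split can lie far above that average. Without 2'-FL A the counts were 187 and 203 and the region from 2227375 stayed higher, by 3.77 on the log2 scale, whereas the higher count was 37 to 67 without any 1 lactose library, 2'-FL B, C or D or LNFP-I B, and the lower count 54 to 81 without lactose A, B or C or 2'-FL B, C or D. With library totals as the scaling the counts fell to 23 and 33, and with upper-quartile factors to 46 and 65. They were 14 and 6 within letters A and B, 229 and 281 within C and D, and 178 and 162 with these sets as a block.

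The second comparison asked the same of LNFP-I. A 9.15-kb region of 7 genes from 2089732 to 2098881 rose 60.7-fold with LNFP-I (23.5 to 130), from 25.9 to 93.1 CPM with lactose to 2189 to 3362 CPM, with edgeR adjusted p from 5.77e-07 to 0.000143. Its log2 difference was 6.11 within letters A and B and 5.68 within C and D. The region that rose with 2'-FL rose with LNFP-I as well, by 31.8-fold (17.1 to 56.7), to 1374 to 2018 CPM. With LNFP-I its run of called genes was longer and began at 2222249, with 14 genes. The longest region spanned 44.4 kb and 79 genes, from 1572787 to 1617204, and rose 74.5-fold (14.5 to 310), with 77 genes called. Its log2 difference from lactose was 6.22, 6.90 without LNFP-I D, 6.85 within letters A and B and 5.50 within C and D. Its level was 10.3 to 20.8 CPM with lactose and 3190, 1824, 1370 and 301 CPM in LNFP-I 1, B, C and D, and it took 45.6%, 32.7%, 25.9% and 7.02% of their gene reads. It was also at 630 CPM in 2'-FL A, against 10.4 to 19.9 CPM in the other 2'-FL libraries.

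Among genes chosen by the same rule, those with the largest increases lay in this region. Gene 2765237100 (1593145 to 1593654) rose from 26.1 ± 9.66 to 5126 ± 3673 CPM (SD, n = 4), a log2 fold change of 7.62 ± 1.81 (SE, edgeR adjusted p = 0.00776). Gene 2765237136 (1611497 to 1611655) had a log2 fold change of 7.44 ± 2.09 (SE, edgeR adjusted p = 0.0165) from a level of 0.482 ± 0.214 CPM with lactose, and 6.79 without LNFP-I 1. With library totals as the scaling these log2 fold changes were 6.77 and 6.58. Within letters A and B they were 8.002 and 7.59 without passing the test (edgeR adjusted p = 0.0566 and 0.0789), and within C and D 6.79 and 6.78. Smaller increases were found in 5 genes from 1028287 to 1032266, by 5.32-fold (3.15 to 8.71), and over 8 genes from 1669732 to 1681034, 7 of them called, by 3.74-fold (1.75 to 6.43). Of 20 genes from 942269 to 957776, 18 were called, at a low level of 5.83 to 26.0 CPM against 2.73 to 4.39 CPM.

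Both regions that fell with 2'-FL fell with LNFP-I. The level from 1069111 to 1075503 fell by 1.42 on the log2 scale (-2.002 to -0.791) and that from 2218042 to 2221961 fell by 1.33 (-1.66 to -1.03). In 6 genes from 1923423 to 1929199, among the more abundant at 3944 to 4190 CPM with lactose, the level fell by 1.25 (-1.67 to -0.77). The genes past the threshold with the largest decreases were short. Gene 2765237679 (2311432 to 2311554) fell from 33.8 ± 7.93 to 2.98 ± 1.59 CPM, a log2 fold change of -3.52 ± 0.46 (SE, edgeR adjusted p = 0.000348). Gene 2765237583 (2189542 to 2189664) fell from 46.4 ± 15.2 to 4.81 ± 2.79 CPM, a log2 fold change of -3.28 ± 0.67 (SE, edgeR adjusted p = 0.0038). With library totals these were -4.18 and -3.92. They were -4.67 and -4.66 within letters A and B, the second not past the threshold (edgeR adjusted p = 0.0605), and -2.67 and -2.24 within C and D.

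In all, 413 genes were higher and 388 lower with LNFP-I than with lactose (edgeR, 1902 genes), of which 238 and 69 changed at least 2-fold. The 11 regions that rose held 159 of the 238. In 932 genes, 49.0%, the groups did not overlap, against 2.86% on average over all splits of the 8 libraries. The split depended on the scaling: it was 259 and 730 with upper-quartile factors and 188 and 1120 with library totals, which moved the median log2 fold change of all genes from 0.05 to -0.31 and -0.65. Library totals also shifted the differences of the regions by -0.71 to -0.61. The counts were 142 and 146 within letters A and B and 499 and 519 within C and D.

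**Figure D2:**
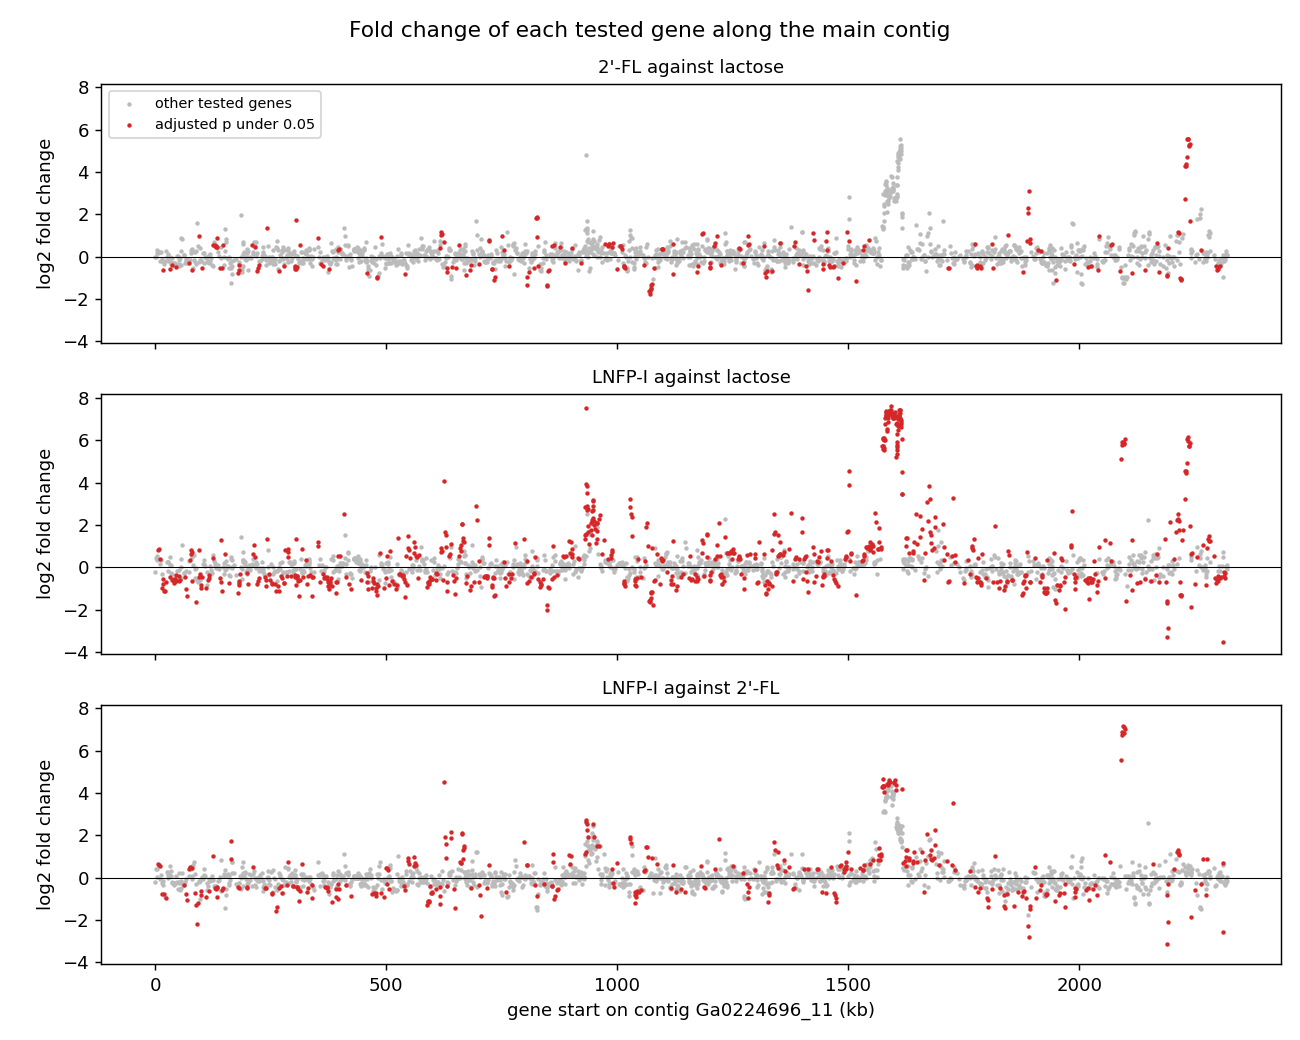
Log2 fold change of each tested gene on contig Ga0224696_11 against its start in kb, for the 3 comparisons, with genes past an adjusted p of 0.05 in red. Genes from 2227375 to 2240645 are raised with both oligosaccharides against lactose, and those from 1572787 to 1617204 pass the threshold with LNFP-I against lactose.

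The third comparison set the related oligosaccharides against each other, each supplied at 2%. The region from 2089732 to 2098881 was 112-fold higher with LNFP-I than with 2'-FL (56.2 to 192), and its 7 genes had edgeR adjusted p from 2.77e-07 to 5.42e-05. Its log2 difference was 6.46 within letters A and B and 7.13 within C and D. With 2'-FL it lay at 17.5 to 39.0 CPM, and its difference from lactose was -0.88 on the log2 scale (-2.41 to 0.59). Gene 2765237508 (2094374 to 2095306) had 1736 ± 291 CPM with LNFP-I and 12.1 ± 5.43 CPM with 2'-FL (SD, n = 4), a log2 fold change of 7.18 ± 0.58 (SE, edgeR adjusted p = 2.76e-05). Gene 2765237510 (2096368 to 2097234) had a log2 fold change of 7.09 ± 0.63 (SE, edgeR adjusted p = 5.42e-05).

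Inside the longest region, 5 genes from 1598017 to 1603217 were all called, at a level 60.9-fold higher with LNFP-I, but with single libraries that overlapped (0.985 to 518), since 2'-FL A lay at 2126 CPM and LNFP-I D at 2095 CPM. The log2 difference was 5.93, and it was 7.20 without 2'-FL A, 5.34 without 2'-FL C and 6.64 without LNFP-I D. In 8 genes from 930596 to 934667, 6 of them called, the level was 3.13-fold higher (0.552 to 9.16). This level was low, at 8.93 CPM in 2'-FL A and 1.98 to 2.46 CPM in the other 2'-FL libraries. Single libraries overlapped here too, since 2'-FL A lay above LNFP-I D (mean log2 CPM of 3.16 and 2.30). In 10 genes from 1565733 to 1575239, a stretch that overlaps the start of the longest region, the level was 6.67-fold higher with LNFP-I (1.17 to 18.1), with all 10 genes called. In 4 genes from 663623 to 667445 the level was 2.90-fold higher with LNFP-I (1.62 to 6.43), and in 5 genes from 2211382 to 2216087 it was 2.46-fold higher (1.11 to 4.32). The genes from 1889431 to 1894247 were lower with LNFP-I, at -1.72 on the log2 scale (-2.92 to -0.74), and 5 genes from 589221 to 594062 were lower, at -1.12 (-1.75 to -0.20). Gene 2765237346 (1890651 to 1892012) had a log2 fold change of -2.79 ± 0.76 (SE, edgeR adjusted p = 0.0326) and gene 2765237679 had -2.58 ± 0.45 (SE, edgeR adjusted p = 0.00502). The first of these rests in size on 2'-FL A, without which its log2 fold change was -1.46, and its call was lost without 2'-FL B or LNFP-I 1, B or C, where edgeR gave log2 fold changes of -2.94 to -2.60 and adjusted p from 0.0528 to 0.0871, and with limma-voom (-1.88, adjusted p = 0.0892). Within letters A and B these genes had log2 fold changes of -4.22 and -3.15, neither past the threshold (edgeR adjusted p = 0.113 and 0.127), and within C and D -0.40 (edgeR adjusted p = 0.168) and -2.28.

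For the region from 2227375 to 2240645 no gene passed the test between the oligosaccharides. The difference was 0.76 on the log2 scale, with an interval from -0.85 to 2.22 that leaves room for a 4.64-fold difference. It was 1.22 without 2'-FL A and changed sign, to -0.11, within letters A and B. The intervals were narrower for the regions that fell with both, 0.09 (-0.42 to 0.75) from 1069111 and -0.26 (-0.77 to 0.39) from 2218042. The longest region was 36.1-fold higher with LNFP-I, but single libraries overlapped (0.477 to 306) because 2'-FL A lay above LNFP-I D, and 19 of its genes were called. The log2 difference was 5.17, and it was 6.57 without 2'-FL A, 4.58 without 2'-FL C and 5.86 without LNFP-I D.

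Between the oligosaccharides, 179 genes were higher and 186 lower with LNFP-I (edgeR, 1902 genes), 84 and 36 of them at least 2-fold. In 364 genes, 19.1%, the groups did not overlap, against 2.86% on average over all splits of the 8 libraries. Genes vary together, so a single split can lie far above that average. A split that mixed the sugars called 531 genes with edgeR, more than the 365 of the real split. Without 2'-FL A the counts were 466 and 416, whereas without 2'-FL B, C or D or LNFP-I 1, B or C they were 79 to 105 and 77 to 100. With upper-quartile factors they were 124 and 585 and with library totals 70 and 1074, with a median log2 fold change of -0.31 and -0.58 against -0.01. The shift of the regions with library totals was -0.59 to -0.54. The counts were 9 and 1 within letters A and B, 482 and 453 within C and D, and 296 and 274 with these sets as a block.

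**Figure D3:**
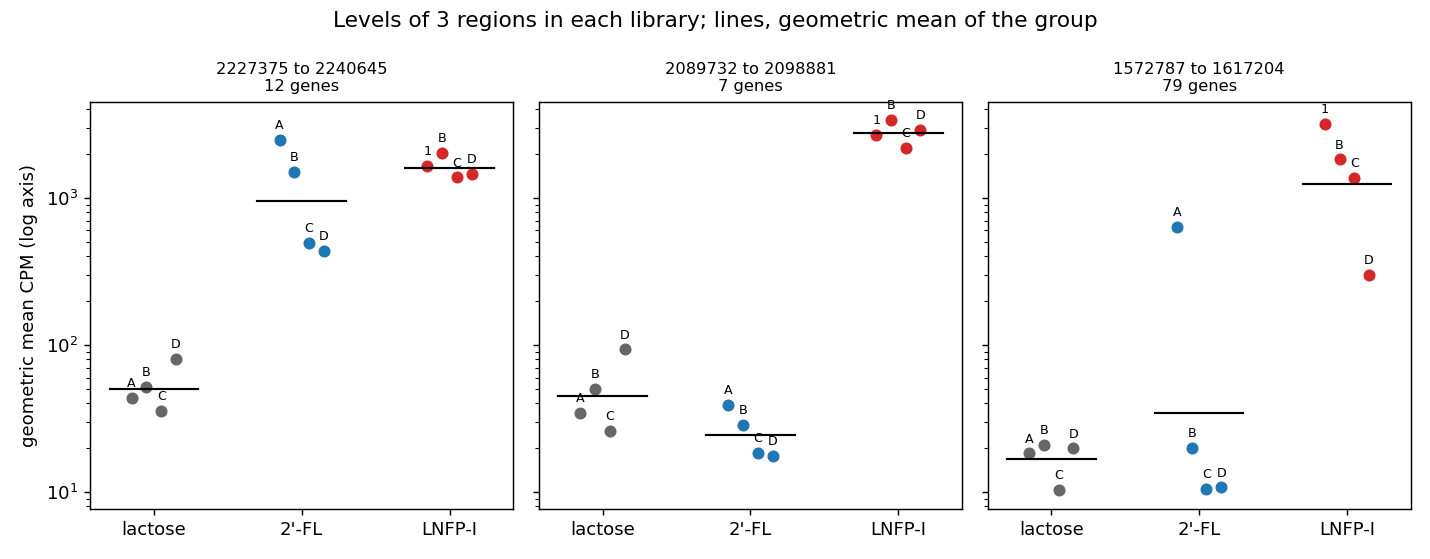
Geometric mean CPM (log axis) of 3 regions in each library, with replicates marked and lines at the geometric mean of each group. The region from 2227375 is at 36 to 80 CPM with lactose and at least 435 CPM elsewhere, that from 2089732 is above 93.1 CPM with LNFP-I alone, and that from 1572787 is raised in the LNFP-I libraries and 2'-FL A.

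The genes called with each oligosaccharide overlapped. Of the genes called with 2'-FL, 69.6% were called in the same direction with LNFP-I, 54 higher and 104 lower, against 22.8 and 24.9 for independent lists, and 3 were called in opposite directions. These 158 genes became 91, 75 and 102 without lactose A, B and C. Without 2'-FL A the share was 55.4%, with 74 genes higher and 142 lower in both, against 50.1 and 52.3 for independent lists, and 47 in opposite directions. The 2 comparisons share the lactose libraries. Unchanged groups simulated against the same controls gave an average overlap of 0 genes, and 0.05 without 2'-FL A. With no gene changed, few calls are expected in either comparison. The simulated overlap therefore cannot show how much the shared controls add when many genes are called. With the controls split so that each comparison used different lactose libraries, and fewer in each fit, the overlap averaged 4.17 genes over 6 splits (0 to 25), and 72.2 genes (11 to 212) without 2'-FL A.

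Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a correlation of 0.83 and a covariance of 1.19, but both values rest on 2'-FL A. Without it they were 0.12 and 0.11, whereas without any other single library they were 0.82 to 0.85 and 1.11 to 1.34. The longest region, with 79 genes, differed from lactose by 6.22 on the log2 scale with LNFP-I. With 2'-FL it differed by 1.05, and by -0.35 without 2'-FL A. How far the correlation and covariance rest on these neighbouring genes was not tested. The simulated unchanged groups had an average correlation of 0.52 and covariance of 0.07, and 0.47 and 0.03 without 2'-FL A. With no gene changed, the shared lactose libraries alone give such a correlation. It is therefore no background for a correlation between responses in which many genes change. The covariance without 2'-FL A lay above the highest of 20 simulated values, 0.044. With the controls split, the covariance averaged 1.15, and 0.0871 (0.00187 to 0.197) without 2'-FL A.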

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

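The tests of other splits and of the component without the longest region were set before their results were seen. The tests of a wrong label, of carry-over, of thinning (both measures, after a single earlier resampling had been seen) and of DNA, shared reads, scaling and gene length in the longest region were chosen after.

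In 117 groups of 4 libraries, the highest or lowest library was set against the others by its gap relative to the group's range. This picked out 13, where chance gives about 1 in 20, or 5.85. All but 1 were 2'-FL A, and the measures overlap in genes and are not independent. 2'-FL A lay at 29.2 on the first component. It was the highest 2'-FL library in the regions from 942269 (11.3 CPM), 1028287 (74.8 CPM), 1496185 (462 CPM), 1572787 (630 CPM), 2278367 (338 CPM), 930596 (8.93 CPM) and 1565733 (166 CPM). It was the lowest in the region from 1069111 to 1079513 (150 CPM), in that from 1923423 (1674 CPM, others 3466 to 3791), and for genes 2765237679 (6.02 CPM) and 2765237583 (5.52 CPM). The remaining library was lactose B, at 35.02 CPM in the region from 1669732 against 29.3 to 29.7 CPM in the others.

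The place of 2'-FL A among the LNFP-I libraries could come from a wrong label, carry-over or depth. Against an LNFP-I culture under its label, the region from 2089732 lay in 2'-FL A at 1.78% of the lowest LNFP-I library and within the lactose range. Against carried-over LNFP-I RNA or reads, that region allows a share of at most 1.78%, while the longest region needs at least 19.1%. The region from 2089732 was picked as higher with LNFP-I than with lactose and than with the 2'-FL group. That group includes 2'-FL A, so a low level there was part of the choice. Among other regions raised with LNFP-I, 2'-FL A lay within the LNFP-I range from 1028287, above it from 2278367 and below it from 663623. Against depth, at least 96.5% of the gap to the nearest other 2'-FL library was left in 20 thinnings to the smallest total, but a second measure was undecided, since the gap was 0.824 to 0.858 of the range and passed its critical share in 15 of 20. Without the 79 genes of the longest region the gap was still 0.845 of the range; the growth state of that culture was not tested and stays open.

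The rise of the 44.4-kb region with LNFP-I, graded among the LNFP-I libraries and present in 2'-FL A, may have a technical or a biological source. The slope of log2 RPKM with LNFP-I on that with lactose across its genes argues against an even DNA signal added to the RNA. This slope was 0.97 (0.87 to 1.08, 95% bounds from resampled genes), where added DNA gives a slope near 0. Neighbouring genes are not independent replicates, so the bounds do not measure the spread between cultures. DNA under both conditions stays open. Reads shared with other copies are argued against by the difference with unique reads, 6.23 against 6.22 on the log2 scale, and scaling by the difference with library totals, 5.52. A hypothesis is that the region is a mobile element, such as a prophage, that was active in some cultures. Its median coding length, 417 bases against 921 over the contig, lay at percentile 0.273 of runs of as many neighbouring genes, which is consistent with this but identifies no gene, and no sequence was used here.

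Other splits of the same 8 libraries into groups of 4 were counted for each comparison, 35 splits each. For 2'-FL against lactose only 1 split, the real one, called as many as 227 genes, with 61 the highest of the others, for lactose and 2'-FL A and B against C and D, and for LNFP-I against lactose only 1, the real one, called as many as 801, with 0 the highest of the others. The real split ranked first in both comparisons, the most that 35 splits can show. Every other split mixes the sugars, which widens the spread within its groups, so this ranking alone does not exclude chance. The 61 genes follow the letters, which points to a structure shared by lactose and 2'-FL. The same split by letter, with LNFP-I 1 as A, called 0 genes in the other 2 comparisons. For LNFP-I against 2'-FL, a split that crossed the letters, 2'-FL A and B with LNFP-I C and D, called 9. The real split of LNFP-I against 2'-FL did not rank first alone, since 2 splits called at least its 365 genes. The other, with 531 genes, set 2'-FL A with LNFP-I 1, B and C against LNFP-I D with 2'-FL B, C and D, which points to a structure of the samples other than their labels.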

How the results depend on the processing

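Counts are given as higher and lower. The alternatives were planned except where said to be added, and the cause of a change was not tested unless given. Counts for 2'-FL against lactose (105 and 122) became 46 and 65 with upper-quartile factors, 23 and 33 with library totals, 211 and 209 with DESeq2, 52 and 69 with only the groups compared, 31 and 19 at 2-fold, and 29 and 37 at adjusted p under 0.01. Counts for LNFP-I against lactose (413 and 388) became 259 and 730 with upper-quartile factors, 188 and 1120 with library totals, 238 and 69 at 2-fold, and 230 and 220 at adjusted p under 0.01. Counts for LNFP-I against 2'-FL (179 and 186) became 124 and 585 with upper-quartile factors, 70 and 1074 with library totals, 65 and 77 with only the groups compared, 84 and 36 at 2-fold, and 42 and 41 at adjusted p under 0.01; the higher count was 285 with DESeq2 and 308 with limma-voom. Stricter thresholds call fewer genes by construction. With 1 library left out, 2'-FL against lactose gave 37 to 187 higher and 54 to 203 lower: 187 and 203 without 2'-FL A, 65 and 81 without B, 60 and 80 without C, 62 and 76 without D, 50 and 62 without lactose A, 37 and 54 without lactose B, 57 and 76 without lactose C, 64 higher without lactose D, and 67 higher without LNFP-I B. LNFP-I against lactose gave 338 to 511 and 287 to 491. LNFP-I against 2'-FL gave 79 to 466 and 77 to 416: 466 and 416 without 2'-FL A, 84 and 100 without B, 79 and 87 without C, 82 and 81 without D, and 90 and 80, 82 and 77, and 105 and 92 without LNFP-I 1, B and C. The shared response (158 genes) ranged from 75 to 216, with 91, 75 and 102 without lactose A, B and C, and averaged 4.17 with the controls split and 72.2 with 2'-FL A left out as well. Added after the data were seen, leaving out 2'-FL A took the correlation of both responses across genes from 0.83 to 0.12 and their covariance from 1.19 to 0.11, and leaving out 2'-FL A and LNFP-I D together gave 194 and 217 for 2'-FL against lactose and 484 and 400 for LNFP-I against 2'-FL; unique reads and leaving out the longest region stayed within 1.5 times. A replicate block by letter, with LNFP-I 1 as A, gave 287 higher for LNFP-I against 2'-FL; the other blocked counts stayed within 1.5 times. The log2 fold change of gene 2765237136 (7.44) was 10.46 with LNFP-I 1 alone in the block and 8.66 with it as A, that of 2765237100 (7.62) was 7.01 with it as A, and that of 2765237346 (-2.79) was -1.58 with it alone. Single letters did not meet the rule for pairing, which asks for every pair above 0.1: deviations of same-letter libraries correlated from -0.20 to 0.71, 6 of 10 pairs above 0.1, and 0 libraries correlated best with their own letter in both other groups. Deviations from the group means mostly followed A and B against C and D. By the replicate chi-square per degree of freedom, only the lactose libraries fell into these sets. With 2'-FL, B lay nearer C and D (293 and 255) than A (821). With LNFP-I, C lay nearer B (103) than D (573). The split into A and B against C and D was added after the data were seen, with LNFP-I 1 as A. As a block it gave 178 higher for 2'-FL against lactose and 296 higher for LNFP-I against 2'-FL. With A and B alone the counts were 14 and 6, 142 and 146, and 9 and 1 for the comparisons in the order above; with C and D alone they were 229 and 281, 499 and 519, and 482 and 453, each from fewer samples. Of the values for named genes under the alternatives, 237 stayed past the threshold and 15 did not, 8 of them in 1 set of letters alone and the others all for gene 2765237346 (among them the blocks by single letter, with edgeR adjusted p of 0.191 and 0.0741); no direction of a named gene reversed. Of the region differences, 1119 stayed within 1 SD and 69 moved; 24 changed sign, all of differences whose interval spans 0, among them, for 2'-FL against lactose without 2'-FL A, the regions from 1572787 (1.05 to -0.35), 1598017 (0.83 to -0.44) and 942269 (0.34 to -0.12). Tests of gene lists and ribosomal RNA rows were not run, since IDs have no names here. At these depths and this spread between replicates, 67% to 79% of simulated 2-fold changes were recovered, so some changes of that size are missed. The simulation changed 200 genes evenly in both directions and raised no region to a large share of the reads. It also drew each gene on its own, so no simulated library departed across many genes as 2'-FL A does. These rates need not carry over to any of the real comparisons.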

Other observations

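All tests here were chosen after the calls had been seen. Genes called in the same direction lay side by side more often than in random gene orders, in 81 neighbouring pairs for 2'-FL against lactose (13.5 on average at random), 452 for LNFP-I against lactose (168) and 151 for LNFP-I against 2'-FL (34.9), each with a permutation p of 1e-04, the smallest these permutations can give. This is consistent with neighbouring genes responding together, though without strand the data do not say which are transcribed as a unit.

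Across genes, the deviation of 2'-FL A from the other 2'-FL libraries had a correlation of 0.83 with the LNFP-I response against lactose, and 0.58 without the longest region and the region from 2089732. Genes are not independent replicates. A hypothesis that 2'-FL A shows the whole LNFP-I response at a lower strength was argued against by 1 of the 3 regions raised over 16-fold with LNFP-I. That region, from 2089732, lay within the lactose range in 2'-FL A. In all 3 regions 2'-FL A lay above the other 2'-FL libraries by at least 1 SD between LNFP-I libraries. The region from 2222249 rose in the other 2'-FL libraries as well. A lower strength in part of the response stays open. There were 24 genes over 10 CPM at more than 2-fold the highest other library in 2'-FL A, against 0 to 6 in each other library. They included 3 neighbouring genes from 2260097 to 2263262, at 290, 306 and 532 CPM against 34.7, 36.3 and 64.3 CPM in the next highest library.

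The small contig, Ga0224696_12, held 0.173% to 0.708% of gene reads per library, of which 0.152% were unique over all libraries. Of its 30 genes, 24 had the same length as a gene with shared reads between 2115692 and 2173869 on the large contig. Counts for these genes are uncertain.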
